A study of Mus musculus with 14 samples.

How the data were processed

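The samples are total RNA of mouse testis from both genotypes, 8 of the younger age in equal parts and 6 of the older age in equal parts, each on 1 array of the Agilent whole mouse genome design with 45018 spots. Per the labels, Cy3-labelled cRNA was hybridized in single colour and the scans were read with Agilent Feature Extraction 9.5. Per the file headers, the deposited scanner files hold intensity values: a mean spot intensity, a local background intensity, and a processed intensity from which the background has been subtracted and trends within the array removed, with no normalization between arrays. They also hold spot flags of 0 or 1. The authors' series table holds the same processed intensity for all 45018 spots of each array, checked spot by spot, and no step between arrays. Slide and scan day were read from the files: 1-week arrays lie on slides 1 to 3 and 4-week arrays on slides 4 and 5. Slide 3 holds only 1-week Glis3KO2 replicate 4, which was scanned on another day than the rest of its age.

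The processed intensity was put on the log2 scale, spots marked as non-uniform were left out, spots of 1 probe were averaged, and the 75th percentile of the non-control probes of the array was subtracted. The 41174 probes were given current gene names through their accession (23082), their symbol (6582) or a synonym (3073), and 8437 kept the name in the file, which gave 27666 genes. A probe entered a comparison when it was well above background on at least 3 arrays of at least 1 of its groups, and the brightest probe stood for a gene with several. Positions are those of the deposited mm7 annotation. Between 74.3% and 86.6% of the non-control spots were well above background on an array.

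Genes were tested with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes), in a separate fit for each age, for WT between the ages, and in 1 fit of all 14 arrays for the difference of the 2 genotype effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of genes are from limma. Where 1 group was at background on all arrays, the fold is a lower bound taken against the background level. The 23 gene lists were fixed from textbook markers before the data were examined, as were the rule for naming genes and the first set of alternatives. They cover germ cell stages, somatic cell types of the testis, neighbouring tissues, and pathways linked to thyroid hormone, hedgehog, retinoic acid, cholesterol, the cell cycle, p53 and the immediate early response. Lists were tested with camera at a preset correlation of 0.01 when at least 5 members were measured in the fit, with adjustment over the lists, and again with an estimated correlation and with fry, which asks only whether the genes of a list move 1 way on balance. List means per array and Glis3 were also compared by exact two-sided permutation tests. The genes named are Glis3, the 8 largest changes per direction at each age among called genes above background in both groups with no overlap of arrays, the 4 largest lower bounds per direction, the 4 largest per direction in the other comparisons, and up to 4 members of each list with the smallest p; further list members are named as examples of their group. Genes known only by a clone or accession name were passed over. Some genes that meet this rule are not reported here. Other probes of a gene were compared for the genes that the rule names, and not for the further list members.

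The alternatives were median scaling, quantile normalization, normexp background correction with an offset of 50, no filter, a filter on all arrays, the mean of all probes, 1 fit of all arrays, slide and replicate blocks, an intensity trend with robust moderation, and leaving out each array. Alternatives added after seeing the data leave out probes that match the telomeric repeat, use 1 slide at a time, keep the brighter part of the genes, compare each list member with up to 100 genes of nearest brightness outside the lists, or keep only genes measured at both ages. The 4-week counts without Glis3KO2 replicate 3 belong to the set that leaves out each array, and were chosen for printing in the text after seeing the data. Whether a list reversed in an alternative is judged by the sign of its median, a rule that replaced the direction given by camera after a first table had been seen. The repeat score is the best ungapped local match to repeated CCCTAA, with 1 per match and -1 per mismatch, and a score of 7 or more counts as a match. The procedure was tested on simulated data: of genes given a log2 change of 2, 80% were recovered in the 1-week design and 65.6% in the 4-week design, and of genes given a log2 change of 1, 43.6% and 29.1%. Only 90 genes were changed by 2 and 110 by 1, with noise independent between genes and no slide effect. These rates are therefore not the power of the real comparisons, where 14645 genes were called at 4 weeks. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Control spots were left out of all tests.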

Results

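Messenger RNA was measured in whole testis of C57BL/6 mice on Agilent single-colour arrays of 60-base probes. Glis3 encodes a zinc finger transcription factor related to the GLI proteins of hedgehog signalling, and Glis3KO2 is the label of the mice in which it was disrupted. The arrays cover 4 WT and 4 Glis3KO2 samples at 1 week and 3 WT and 3 Glis3KO2 samples at 4 weeks. The sample labels give 4 weeks for the older mice while the series description gives 3 weeks, and the sample labels are followed here. The labels do not say that the samples are separate animals, so each p-value measures only the spread between samples. Between 74.3% and 86.6% of the 43379 non-control spots of an array were well above background, and the number of arrays limits the precision. This share was 82.6% to 86.6% on 1-week WT replicates 1 to 3 and 74.3% to 78.5% on 1-week WT replicate 4 and the 1-week Glis3KO2 arrays. The values below are log2 signals relative to the 75th percentile of each array, and each log2 difference is Glis3KO2 minus WT unless another contrast is named.

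Age separated the samples more than genotype did. The first principal component of 23496 genes held 81.5% of the variance and parted the 1-week arrays from the 4-week arrays, with 4-week Glis3KO2 between the 1-week arrays and 4-week WT. Across genes, which are not independent replicates, the correlation between arrays was 0.962 to 0.987 between WT and Glis3KO2 at 1 week and 0.898 to 0.959 at 4 weeks. Within groups it was 0.976 to 0.995 for 1-week WT, 0.977 to 0.992 for 1-week Glis3KO2, 0.993 to 0.995 for 4-week WT and 0.974 to 0.990 for 4-week Glis3KO2. 1-week WT replicate 4 correlated at 0.976 to 0.983 with the other WT arrays. With Glis3KO2 replicates 1 to 4 it correlated at 0.984, 0.987, 0.970 and 0.973. On the second component it lay at 0.76, against -66.9 to -45.3 on the other 1-week WT arrays and -3.36 to 36.5 on 1-week Glis3KO2. The 1-week arrays thus did not group fully by genotype.

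The first question was whether the array shows the loss of Glis3 itself. Glis3 was lower in Glis3KO2 at 1 week: its log2 signal was -4.87 ± 0.18 (SD, n = 4) in WT, above background on 4 of 4 arrays, and -8.04 ± 0.84 (SD, n = 4) in Glis3KO2, above background on 0 of 4. Glis3 is represented by 1 probe of 60 bases on chromosome 19, drawn on the mm7 genome build from 28054217 to 28057750, a span of 3534 bases, and its place relative to the disrupted part of the gene is not known. By the rule used for the telomeric repeat below, this probe itself counts as a match, with the lowest counting score of 7, so Glis3 has no value when matching probes are left out. The log2 difference was -3.17 (SE 0.38, limma adjusted p = 0.0059), and the exact two-sided permutation p was 0.0286, the smallest that 4 arrays against 4 can give. Because the Glis3KO2 arrays lay at background, the fold is a lower bound taken against the background level: Glis3 was at least 4.25-fold lower in the main processing. With another background correction the log2 difference was -0.46 and its adjusted p 0.205, against a range of 0.00067 to 0.205 over all alternatives. The bound therefore depends on how the background is treated. At 4 weeks the Glis3 probe was above background on 0 of 3 WT and 0 of 3 Glis3KO2 arrays, so no fold is given (exact permutation p = 0.3, smallest possible 0.1).

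The second question was which transcripts differ in the young testis, before the meiotic and spermatid stages have built up. Genes of undifferentiated spermatogonia, the cells that hold the stem cells of spermatogenesis, were lower in 1-week Glis3KO2. Of 25 measured genes in this list 19 fell, 22 when adjusted over the list alone, and 0 rose, with a median log2 difference of -1.76. They included Lin28a, an RNA-binding protein (-3.61, SE 0.58), Piwil4, a piRNA-binding protein (-2.86, SE 0.30), the transcription factors Pou5f1 (-2.75), Neurog3 (-2.25), Sox3 (-2.21) and Bcl6b (-1.76), the translational regulator Nanos3 (-2.55), and Gfra1, the co-receptor for GDNF (-2.17). Tspan8 (0.40), Cdh1 (-0.0044), Sall4 (-0.48), Taf4b (-0.62), Utf1 (-0.76) and Nanos2 (-1.73) did not pass the test. Of 10 genes that respond to GDNF, a factor that maintains spermatogonial stem cells, 7 fell, 9 when adjusted over the list alone, with a median of -1.74. Egr2 (-1.96), Egr4 (-2.56), Pou3f1 (-1.85), Lhx1 (-1.71), Etv5 (-1.01), Bcl6b and T (-2.68, at least 2.22-fold lower) made up these 7, and 7 of the 10 members are also in the spermatogonial list. The Etv5 probe has the lowest counting score of 7 for the telomeric repeat described below and the Tspan8 probe a score of 8, and a second Etv5 probe gave -0.35. Eomes of the spermatogonial list was at least 3.18-fold lower. With another background correction the calls of T (-0.23, adjusted p = 0.5) and Eomes (-0.28, adjusted p = 0.397) were lost, so these bounds depend on how the background is treated.

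Both lists passed the camera test, with adjusted p = 3.3e-12 for undifferentiated spermatogonia and 1.2e-06 for the GDNF list, and neither call held with an estimated correlation, where the adjusted p was 0.154 for each. The mean of each list was lower on 4 of 4 Glis3KO2 arrays than on every WT array (exact permutation p = 0.0286, the smallest possible; adjusted over the lists 0.0821). With slide as a block the medians were -1.56 and -1.54. The median of the spermatogonial list was -1.28 on slide 1, which holds 2 arrays of each genotype, and -1.77 on slide 2, which holds 2 WT arrays and 1 Glis3KO2 array. The corresponding medians of the GDNF list were -1.24 and -1.94.

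**Figure D1:**
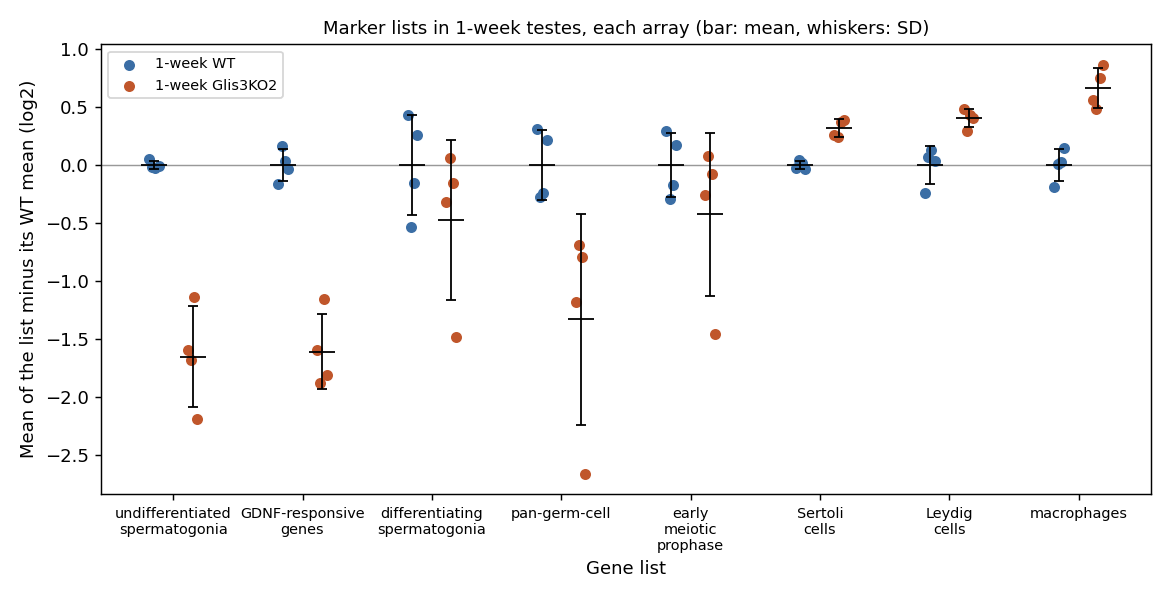
Mean log2 signal of 8 gene lists on each 1-week array, minus the mean of the WT arrays, with points for arrays, bars for group means and whiskers for the SD (n = 4 per group). The Glis3KO2 arrays lie between -2.19 and -1.14 for undifferentiated spermatogonia and between 0.24 and 0.39 for Sertoli cells, against -0.03 to 0.05 and -0.03 to 0.04 for the WT arrays.

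Among 16 genes expressed across germ cells, 3 fell at 1 week, 11 when adjusted over the list alone, with a median of -1.37. Replicate 4 of Glis3KO2, alone on its slide and scanned on another day, stood apart here, with a list mean of -2.66 relative to WT against -1.18 to -0.69 on the other 3 arrays; without it the median was -0.97. The 3 were the piRNA pathway genes Tdrd1 (-2.13) and Piwil2 (-1.74) and the germ cell survival factor Dnd1 (-1.41), while Ddx4 (-1.49) and Dazl (-0.90) did not pass. Of 11 genes of differentiating spermatogonia 3 fell, the receptor Kit (-1.15), the DNA methyltransferase Dnmt3b (-1.07) and Lmo1 (-1.76), also 3 when adjusted over the list alone, and Stra8 (-0.73) did not pass. Of 21 genes of early meiotic prophase 0 passed in either adjustment, with a median of -0.34. In these 2 lists replicate 4 again stood apart, with means of -1.48 and -1.46 against -0.31 to 0.06 and -0.26 to 0.08 on the other 3 Glis3KO2 arrays. Of 20 pachytene genes 6 fell and 1 rose, 8 and 1 when adjusted over the list alone. The germ cell lactate dehydrogenase Ldhc (-3.33) and the piRNA-binding Piwil1 (-3.06) were lowest, and Pgk2 (1.71) was the one that rose, with a probe that matches the telomeric repeat described below. Of 16 round spermatid genes Papolb (-0.81) and Izumo1 (-2.08) fell, and of 13 elongating spermatid genes Akap4 and Hils1 fell, at least 1.29-fold and 1.52-fold; Papolb and Hils1 changed sign with another background correction, to 0.030 and 0.036, and the Akap4 call was lost with it (-0.06, adjusted p = 0.865). Adjusted over the list alone these counts were 2 and 3. The calls of Kit and Lmo1 were lost in 9 and 10 of 20 alternatives, those of Papolb and Izumo1 in 10 of 18 each and that of Hils1 in 13 of 18. By camera the adjusted p was 4.5e-05 for the pan-germ-cell list, 0.0378 for the pachytene list and 0.0275 for the elongating spermatid list, against an adjusted p of 0.725 for each with an estimated correlation. The pan-germ-cell call was also lost with fry (adjusted p = 0.0993). The differentiating (0.225), early meiotic (0.225) and round spermatid (0.656) lists were not called. The differentiating list was called in 3 of 22 alternatives (median as low as -0.76, lowest adjusted p = 0.0023) and the early meiotic list in 2 of 22 (lowest adjusted p = 0.0122), so a fall at these stages is not ruled out. With slide as a block the medians were -0.98 for the pan-germ-cell list, -0.39 for the pachytene list and -0.56 for the elongating spermatid list, whose median was -0.77 on slide 1 and -0.12 on slide 2. The pachytene and elongating spermatid calls were each lost in 7 of the alternatives, among them quantile normalization and the stricter filter. The pachytene call was also lost without WT replicate 1 or 4 and the elongating spermatid call without Glis3KO2 replicate 1. Relative to genes of like brightness, a comparison chosen after seeing the data, the pachytene mean differed by -0.49 (exact permutation p = 0.0571) and the elongating spermatid mean by -0.09 (exact permutation p = 0.571), both with overlapping arrays, so neither fall is told apart from the fall of dim probes as a whole. By the same comparison the pan-germ-cell mean differed by -1.40 with no overlap (exact permutation p = 0.0286, the smallest possible).

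Genes of several somatic cell types were modestly higher in 1-week Glis3KO2. Of 25 Sertoli cell genes 6 rose, 9 when adjusted over the list alone, with a median of 0.33; they included anti-Müllerian hormone Amh (0.97), desert hedgehog Dhh (0.87), the inhibin subunits Inha (0.82) and Inhbb (0.73, with 0.17 on a second probe) and the cystatin Cst12 (0.74). Of 16 genes of Leydig cells, which make androgens, 5 rose, also 5 when adjusted over the list alone, with a median of 0.38; among them were the peptide hormone Insl3 (0.64), the steroidogenic enzymes Hsd3b1 (0.63) and Hsd3b6 (0.56) and the prostaglandin synthase Ptgds (1.12). Of 15 genes of macrophages and other immune cells 7 rose, 12 when adjusted over the list alone, with a median of 0.62; these included the antigen presentation genes H2-Ab1 (1.00) and H2-Aa (0.78), the macrophage receptor Adgre1 (0.81, with 0.24 on a second probe), lysozyme Lyz2 (0.97) and Cd74 (2.13), whose probe matches the telomeric repeat. The calls of Inha, Inhbb and Hsd3b1 were lost in 10 of 20 alternatives each, Hsd3b6 in 11 of 20, Insl3 and Ptgds in 9 of 20 each and H2-Aa in 9 of 19. For these lists camera gave an adjusted p of 0.0011 for Sertoli cells, 0.0020 for Leydig cells and 1.2e-06 for immune cells, and with an estimated correlation the adjusted p was 0.154, 0.154 and 0.274. All 4 Glis3KO2 arrays lay above every WT array in these 3 lists (exact permutation p = 0.0286, the smallest possible; adjusted 0.0821). With slide as a block the medians were 0.30, 0.41 and 0.57; on slide 1 they were 0.33, 0.50 and 0.60, and on slide 2 they were 0.26, 0.33 and 0.31. Without probes that match the repeat, an alternative chosen after seeing the data, 13 immune genes had a median of 0.62 (camera adjusted p = 2.7e-05, and adjusted p = 0.37 with an estimated correlation). Bright probes as a whole were higher in Glis3KO2, with a median of 0.24 in the brightest of 4 equal groups of genes. Relative to genes of like brightness, a comparison chosen after seeing the data, the list means still differed by 0.20 for Sertoli, 0.42 for Leydig and 0.73 for immune genes, with no overlap of arrays (exact permutation p = 0.0286 each, the smallest possible).

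The remaining lists were not called at 1 week. The camera adjusted p was 0.194 for peritubular cells and for blood, with 0 of 10 and 0 of 6 members past the test. The p was 0.243 for endothelial cells, where Emcn rose (0.64), and 0.445 for adipose tissue, where the lipid-handling genes Fabp4 (1.72) and Plin1 (0.78) rose. It was 0.656 for thyroid hormone genes, where Dio3, the enzyme that inactivates thyroid hormone, fell (-1.20) and Thrsp rose (0.72). In the hedgehog list (adjusted p = 0.671) Dhh and Glis2 (0.42) rose and Gli3 fell (-0.52, with -1.21 on a second probe), with 3 higher and 3 lower when adjusted over the list alone. In the retinoic acid list (adjusted p = 0.671) the retinoic acid hydroxylase Cyp26a1 (-1.48) and the receptor Rarg (-0.66) fell and the synthetic enzyme Aldh1a3 rose (0.66), while another Aldh1a3 probe gave -0.08. In the cholesterol list (adjusted p = 0.0558) 3 genes fell, among them Lss (-0.96) and Insig1 (-1.35), and adjusted over the list alone 5 were lower and 1 was higher; another Lss probe gave 0.18, and the list was called in 9 of 22 alternatives, with an adjusted p as low as 0.00013. With an estimated correlation its adjusted p was 0.725, and median scaling turned its median from -0.24 to 0.0153. It was 0.929 for the cell cycle list, where Ccnb1 fell (-0.81) but another Ccnb1 probe did not (0.23), 0.389 for p53 targets, where Phlda3 rose (0.62), and 0.929 for immediate early genes, where 0 of 11 passed. Adjusted over the list alone, 0 members of the cell cycle, p53 and immediate early lists passed, and the counts of the endothelial, adipose, thyroid and retinoic acid lists stayed as given. The calls of Glis2 (15 of 20), Gli3 (12 of 20), Ccnb1 (12 of 20), Phlda3 (10 of 20), Aldh1a3 (9 of 20), Rarg (12 of 19) and Fabp4 (12 of 19) were lost in the given number of alternatives. Median and mean differed in sign for the adipose, thyroid, hedgehog, retinoic acid, cell cycle and immediate early lists. Of the 12 epididymis genes 5 were measured and 0 passed (median -0.13); camera was not run on this list, because it takes only genes with a value on every array and fewer than 5 were left. Chosen after its values were seen, Crisp1 of this list, which did not pass the filter at 1 week, had log2 signals of -0.69 and -0.0042 on Glis3KO2 replicates 1 and 4, against -9.26 to -7.29 on the WT arrays and -8.08 and -6.99 on Glis3KO2 replicates 2 and 3. Defb20, a defensin of the same list, was at -3.44 and -4.75 on replicates 1 and 4, against -6.16 to -5.78 on 3 WT arrays and -6.47 and -6.42 on the other replicates. The median of the 7 list genes measured at either age was 0.0064 and -0.50 relative to WT on these 2 arrays, within the WT range of -0.61 to 0.39, while the mean was 1.31 and 0.83, above the WT range of -0.65 to 0.44. Rnase10 was at -7.12 and -8.20 on them, against -7.48 to -6.46 in WT, and Lcn10 at -5.04 and -4.96, against -5.00 to -3.95. The raised mean comes from some genes and not from the list as a whole, and whether these 2 samples hold epididymal tissue stays open.

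Outside the lists, the largest falls among genes above background in both groups were Tmem132e (-4.00, SE 0.26), Tmem63c (-3.22, SE 0.32), Ssxb2 (-3.01, SE 0.52), the membrane junction gene Jph3 (-2.97, SE 0.30), Efcab10 (-2.83, SE 0.61) and Tdh, a threonine dehydrogenase (-2.79, SE 0.36). For each, Glis3KO2 lay below WT on every array, which the rule for naming genes requires. The Jph3 probe has a repeat score of 7, and a second Tmem63c probe gave -2.41. Best3 was at least 4.67-fold lower, although WT replicate 4 (-7.88) lay within the Glis3KO2 range of -9.33 to -7.87, and its call was lost in 8 of 15 alternatives. The call of Efcab10 was lost in 8 of 19 alternatives. The manganese transporter Slc30a10 was at least 4.27-fold lower, the germ cell transcription factor subunit Gtf2a1l at least 3.30-fold and the homeobox gene Dlx4 at least 3.25-fold; another background correction ended these 3 calls, with -0.52 (adjusted p = 0.119) for Slc30a10, -0.38 (adjusted p = 0.255) for Gtf2a1l and -0.37 (adjusted p = 0.275) for Dlx4. The 8 largest rises were Dnajb8 (3.66, SE 0.42), Acot6 (3.57, SE 0.37), Syt6 (3.51, SE 0.39), St6galnac5 (3.50, SE 0.38), Adamtsl3 (3.41, SE 0.35), Evx2 (3.27, SE 0.34), Cpb2 (3.16, SE 0.31) and Erv3 (3.04, SE 0.38). Each of these 8 probes holds a stretch that counts as a match to the telomeric repeat CCCTAA, with scores of 7 to 10. The lower of these scores are common on both strands. On this strand 1064 probes have a score of 7 and 322 a score of 8, against 976 and 309 on the opposite strand. A score of 7 alone did not go with a rise, as 27 of 616 such genes were higher and 40 lower. Of the 48 genes that rose by a log2 of more than 2, 47 had such a match, against 929 of 22468 genes tested, or 4.13%; the repeat was found by looking at these same genes, so this share is not independent evidence. A second Adamtsl3 probe without the match gave -0.14. A second Acot6 probe, which also counts as a match, gave 0.95. Chosen after seeing their values, the 8 largest rises without a match were Cbln1 (2.03), the homeobox gene Rhox3a (1.99), the innate immune receptor Clec7a (1.66), Cnmd (1.56), Cltrn (1.43), Miox (1.43), Rimbp2 (1.40) and Pcp2 (1.38), of which Cbln1 lost its call in 11 of 20, Pcp2 in 9 of 20 and Cltrn in 9 of 19 alternatives.

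Over all genes, 896 were higher and 1372 lower of 22468 tested at 1 week, and 119 and 831 of these changed at least 2-fold. The balance of directions followed the scaling: the median log2 difference of all genes was -0.06 with the 75th percentile and 0.19 with median scaling, under which 2926 genes were higher and 1000 lower. Of 5617 genes in the dimmest of 4 equal groups 23 were higher and 495 lower, and in the brightest group 418 were higher and 86 lower, with medians of -0.61 and 0.24. With slide as a block 66 genes were higher and 429 lower; on slide 1 alone limma called 0 higher and 0 lower, with 4129 genes at an unadjusted p under 0.05. The calls were 79 higher and 279 lower without WT replicate 1, 100 and 463 without WT replicate 2, 83 and 337 without WT replicate 3, 105 and 426 without Glis3KO2 replicate 1, 153 and 679 without Glis3KO2 replicate 4, and 966 and 2565 without WT replicate 4.

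**Figure D2:**
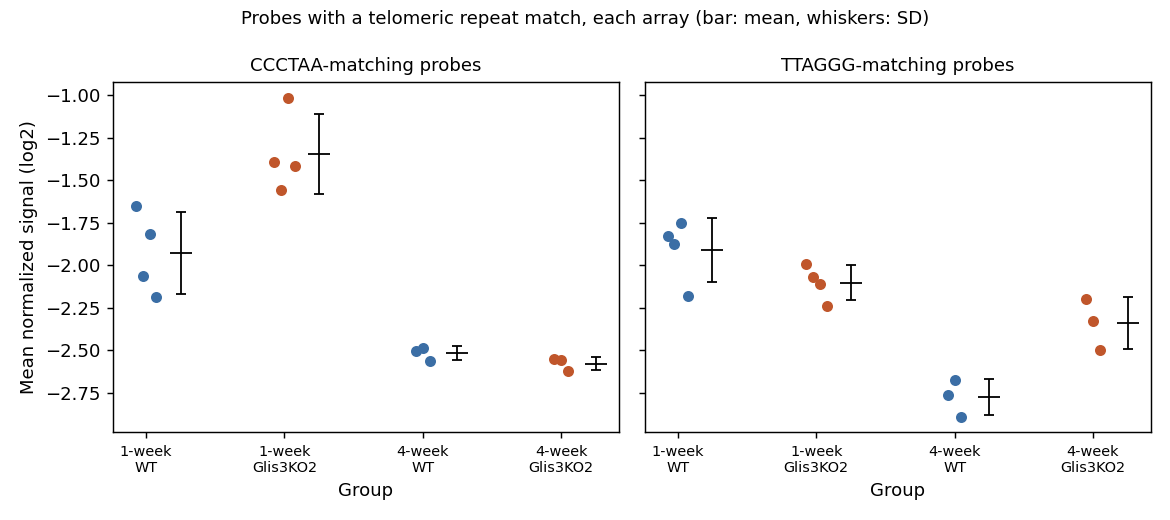
Mean log2 signal on each array of 173 probes that match the telomeric repeat CCCTAA with a score of 9 or more and of 124 probes that match its opposite strand, in the 4 groups, with points for arrays. The matching probes lie between -1.56 and -1.02 on the 1-week Glis3KO2 arrays and between -2.19 and -1.65 on the 1-week WT arrays.

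The third question was how the testis differs at 4 weeks, when WT testes hold spermatocytes and spermatids. Transcripts of meiotic and later germ cells were lower in 4-week Glis3KO2. Of 21 early meiotic genes 20 fell (median -1.40), including the synaptonemal complex genes Sycp1 (-1.40) and Syce2 (-1.27), the cohesin Rec8 (-1.35) and the recombination genes Msh5 (-1.79) and Spo11 (-1.87), while Dmc1 (-0.26) did not pass. All 20 pachytene genes (median -2.15), all 20 round spermatid genes (-2.54) and all 18 elongating spermatid genes (-2.96) fell. Among them were the chaperone Calr3 (-3.20), the kinase Aurkc (-2.43, with a repeat score of 7), the kinase Tssk6 (-3.27), the sperm fusion protein Izumo1 (-2.95), the transition proteins Tnp1 (-3.41) and Tnp2 (-3.90), and the protamine Prm2 (-3.15). Of 16 pan-germ-cell genes 11 fell (median -1.18), including Ddx4 (-1.65) and Tex14 (-1.39), while Dazl (-0.18) and Dnd1 (-0.06) did not pass. Undifferentiated spermatogonial genes went both ways, with 9 of 21 higher, such as Foxo1 (1.48), Pou3f1 (1.62) and Piwil4 (1.05), and 3 lower, Gfra1 (-2.26), Id4 (-0.86) and Lhx1 (-1.49). A second Gfra1 probe gave -0.31. Of 7 GDNF-responsive genes 5 rose, among them Egr2 (2.80) and Tec (2.08), and Lhx1 fell. Of 11 genes of differentiating spermatogonia Ccnd2 (1.68), Kit (0.60) and Lmo1 (0.58) rose and Dmrtb1 (-2.29) and Esx1 (-0.58) fell.

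**Figure D3:**
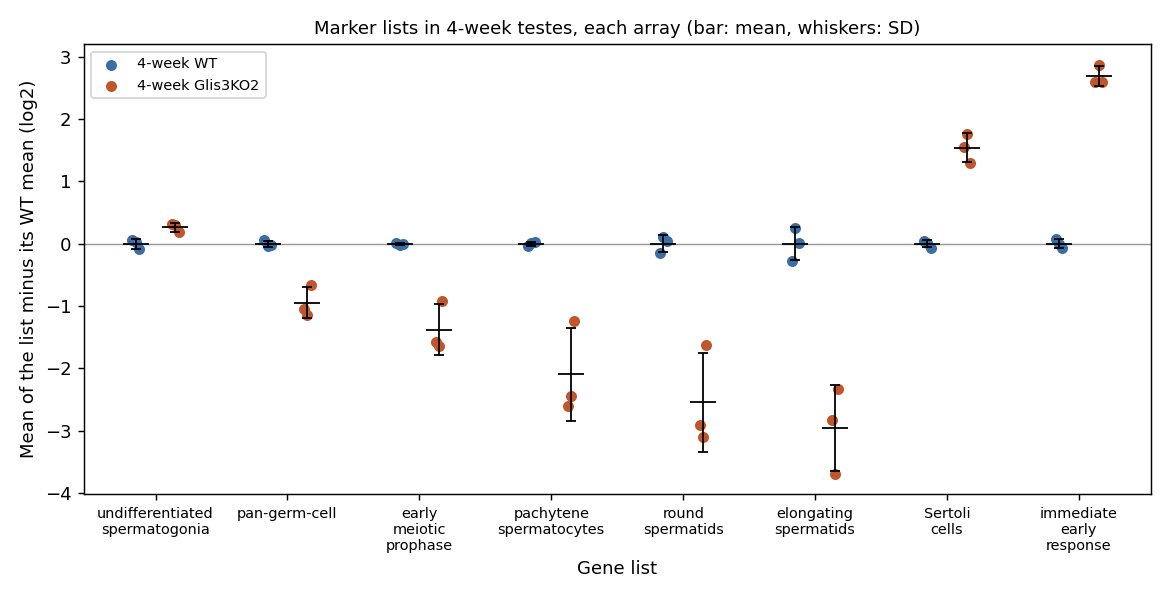
Mean log2 signal of 8 gene lists on each 4-week array, minus the mean of the WT arrays, over members measured at either age, with points for arrays, bars for group means and whiskers for the SD (n = 3 per group). The Glis3KO2 arrays lie between -3.69 and -2.33 for elongating spermatids and between 2.59 and 2.87 for immediate early genes, and replicate 3 is the Glis3KO2 array nearest to WT in the germ cell lists that fell.

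Adjusted over the list alone the falls numbered 20, 20, 20, 18 and 11 in the early meiotic, pachytene, round spermatid, elongating spermatid and pan-germ-cell lists, 8 higher and 3 lower in the undifferentiated list, 5 and 1 in the GDNF list and 1 and 2 in the differentiating list. The camera adjusted p was 7.8e-06, 7.8e-06, 4.1e-06, 4.1e-06 and 0.0058 for those 5 lists, and the undifferentiated (0.342), GDNF (0.122) and differentiating (0.652) lists were not called. By fry the GDNF list was higher (adjusted p = 0.0063), while the undifferentiated (0.0564) and differentiating (0.439) lists were not called. No list called at 4 weeks held with an estimated correlation, where the adjusted p was 0.583 for each. Each mean of the 5 lists was lower on 3 of 3 Glis3KO2 arrays than on every WT array (exact permutation p = 0.1, the smallest that 3 against 3 can give). On slide 4, which holds 2 arrays of each genotype, the elongating spermatid median was -3.21. On slide 5, which holds 1 of each, it was -2.38. With slide as a block it stayed at -2.96, because equal numbers of the genotypes on each slide leave the estimate unchanged.

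Somatic cell genes were mostly higher at 4 weeks, with Leydig cell genes split. Of 25 Sertoli cell genes 19 rose (median 1.93), including the transcription factors Sox9 (2.61), Sox8 (2.40) and Wt1 (2.04), the FSH receptor Fshr (2.48), the stem cell factor Kitl (2.36) and clusterin Clu (2.09). Of 10 genes of peritubular and smooth muscle cells 8 rose, among them the contractile genes Lmod1 (1.78), Tagln (1.47) and Acta2 (1.23), and Actg2 fell (-0.59). Of 15 immune genes 12 rose, with the scavenger receptor Cd163 (2.33) and the complement genes C1qa (1.21) and C1qb (1.14), and H2-Ab1 (-0.50) and Cx3cr1 (-0.71) fell. Of 10 endothelial genes 5 rose, Robo4 (4.86), Pecam1 (1.57), Cdh5 (1.30), Emcn (1.12) and Esam (1.09). Of 16 Leydig cell genes 6 fell and 5 rose: the androgen synthesis enzymes Cyp11a1 (-3.68, SE 0.18), Cyp17a1 (-2.85, SE 0.19), Hsd17b3 (-1.86) and Hsd3b6 (-1.76) were lower, while Star (1.35), which brings cholesterol into mitochondria, the lipoprotein receptor Scarb1 (1.12) and Hsd11b1 (2.43) were higher. The camera adjusted p was 7.8e-06 for Sertoli, 0.0223 for peritubular, 0.0125 for immune, 0.0345 for endothelial and 0.441 for Leydig cell genes, and the adjusted p with an estimated correlation was 0.583 for the first 4. Adjusted over the list alone 20 Sertoli genes were higher, and the other counts did not move. By fry the Leydig cell list was lower (adjusted p = 0.0271). The immune and endothelial calls were lost without Glis3KO2 replicate 3, the endothelial call also without WT replicate 2 and with quantile normalization. The Sertoli median was 2.12 on slide 4 and 1.41 on slide 5. Slide as a block, which cannot move it in this balanced design, gave 1.93.

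Stress, growth control and signalling genes also differed at 4 weeks. They changed beside rises of Sertoli (median 1.93) and peritubular (1.25) genes and falls of meiotic and later germ cell genes. Whole-testis RNA does not separate a change per cell from a changed cell makeup. Dhh is a member of both the Sertoli and the hedgehog list. Of 11 immediate early genes, which respond within minutes to stimuli including tissue handling, 10 rose (median 2.79), with Atf3 (5.47), Jun (3.53), Fos (3.41), Ier3 (3.38) and Egr1 (2.89). Of 15 p53 targets and apoptosis genes 12 rose (median 1.35), among them the death genes Bbc3 (3.04) and Fas (2.11) and the growth arrest gene Gadd45a (2.99), and Mdm2 fell (-1.20). Of 20 cell cycle genes 14 fell (median -1.09), including Birc5 (-1.83), Plk1 (-1.79) and Cdc6 (-1.64), and the replication helicase genes Mcm3 (0.48) and Mcm6 (0.67) rose. Of 13 hedgehog and GLI genes 10 rose (median 1.49), with the ligand Dhh (2.33), the targets Hhip (2.90), Ptch1 (2.35) and Gli1 (1.36), the GLIS family member Glis2 (2.53) and the co-activator Wwtr1 (3.07), and Sufu fell (-0.45); a second Wwtr1 probe gave -0.39 and a second Glis2 probe 0.90. Of 15 retinoic acid genes 8 rose (median 0.88), including the enzymes Aldh1a3 (2.03) and Aldh1a1 (1.46), and Aldh1a2 (-0.42) and Rdh10 (-0.56) fell. Of 16 cholesterol genes 8 fell, such as Insig1 (-2.54) and the sterol demethylase Cyp51 (-2.40), and 5 rose, such as Msmo1 (1.09) and Dhcr7 (1.02); another Insig1 probe gave 0.15 and another Cyp51 probe -0.02. Of 11 thyroid hormone genes 6 rose, with the receptors Thra (3.32) and Thrb (1.85), and the deiodinase Dio2 (-1.54) and Hr (-0.86) fell; of 3 Thrb probes the lowest gave -0.0043. Tested by camera, the adjusted p was 1.3e-05 for immediate early, 0.0042 for p53, 0.0058 for cell cycle, 0.0039 for hedgehog and 0.0473 for retinoic acid genes (adjusted p = 0.583 with an estimated correlation for each), and the cholesterol (0.342) and thyroid (0.255) lists were not called. By fry the cholesterol list was lower (adjusted p = 0.0271) and the thyroid list higher (adjusted p = 0.0111). The counts adjusted over the list alone were the same except for 3 lower retinoic acid genes. The retinoic acid call was lost in 7 alternatives, among them leaving out WT replicate 1 or Glis3KO2 replicate 1 or 2. Slide as a block left the medians of the 5 called lists at 2.79, 1.35, -1.09, 1.49 and 0.88. Each 4-week slide holds the genotypes in equal numbers, so the block cannot move these medians and is no check of them.

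The blood, epididymis and adipose lists, for tissue that could come along with the testis, were not called at 4 weeks (camera adjusted p = 0.652, 0.342 and 0.79), while by fry the blood (adjusted p = 0.0473) and epididymis (adjusted p = 0.0434) lists were lower. Of 5 blood genes Cldn13 fell (-2.45), of 7 epididymis genes the sperm-coating Crisp1 (-4.28) and Rnase10 (-2.01) fell, and of 9 adipose genes the hormone adiponectin Adipoq fell (-2.16) and Cidea rose (1.54), with the same counts when adjusted over the list alone. The Crisp1 signal was uneven in WT, at -0.18, -3.05 and -5.19 on the 3 arrays, and its call was lost in 3 of 16 alternatives.

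Over all genes, 7447 were higher and 7198 lower of 21144 tested at 4 weeks, 5103 and 5066 of them at least 2-fold. The largest rises were Ildr2 (6.02, SE 0.31), the glycosyltransferase Galnt15 (5.83, SE 0.43), the TWEAK receptor Tnfrsf12a (5.82, SE 0.19), brevican Bcan (5.63, SE 0.63), the stress transcription factor Atf3 (5.47, SE 0.31), Wfdc18 (5.36, SE 0.36), the growth factor carrier Igfbp3 (5.01, SE 0.33) and Rasgef1c (4.98, SE 0.32); other probes of Ildr2 and Igfbp3 gave 2.48 and 2.13. Cxadr was at least 23.9-fold, Tmem212 at least 9.60-fold, Nebl at least 8.41-fold and Tnmd at least 8.22-fold higher than WT arrays at background. Another Cxadr probe gave a log2 difference of 1.95. Over the alternatives the log2 difference was as small as 2.75 for Cxadr, 1.99 for Tmem212, 1.61 for Nebl and 1.66 for Tnmd. All 4 calls held, but the size of these bounds depends on the processing. The largest falls were the kallikrein Klk1b27 (-4.37, SE 0.34), Bpifa3 (-4.15, SE 0.52), Cstl1 (-4.10, SE 0.45), Ttc24 (-4.08, SE 0.47), Tex13c3 (-4.08, SE 0.45), Tex46 (-4.08, SE 0.43), Nudt16l2 (-4.02, SE 0.44) and Tnp2 (-3.90, SE 0.43). The nuclear receptor Nr4a3 was at least 8.62-fold, Dsc1 at least 5.42-fold, Frrs1l at least 5.18-fold and Kcna3 at least 5.04-fold lower. The calls of Frrs1l (adjusted p = 0.0537) and Kcna3 (adjusted p = 0.106) were lost with another background correction. The calls of Nr4a3 and Dsc1 held, but over the alternatives their log2 differences were as small as -1.23 and -0.85, so these bounds also depend on the processing. Slide as a block gave 7625 higher and 7356 lower, and slide 4 alone gave 8212 and 7193.

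The genes called at both ages overlapped more often in the same direction than in opposite directions. Of 20083 genes tested at both ages, 554 were higher at both, against 323.3 if the calls were independent, and 630 were lower at both, against 358.3. Higher at 1 week and lower at 4 weeks were 149, against 274.1, and lower then higher were 180, against 422.5. Fisher's exact test gave odds ratios of 3.099 and 2.873 for the shared directions (p = 1.2e-58 and 1.1e-65), counting genes as if they were independent, which they are not.

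The fourth question was whether the effect of Glis3KO2 differs between the ages, tested as the 4-week difference minus the 1-week difference. It did for 12007 of 23529 genes, 6908 with a higher value at 4 weeks and 5099 with a lower one. Undifferentiated spermatogonial genes (20 of 25 with a positive difference, median 2.19) and GDNF-responsive genes (7 of 10, median 1.998) had effects that were less negative or positive at 4 weeks. These values are relative to the whole of each array, and at 4 weeks the undifferentiated median was 0.28 while the Sertoli median was 1.93. Members such as Eomes and T did not pass the filter at 4 weeks, so their difference only restates the fall at 1 week; on the genes that pass it at both ages, a choice made after seeing the data, 17 of 21 (median 2.06) and 6 of 7 (median 2.40) were positive. Round spermatid (18 of 20, median -2.32), elongating spermatid (16 of 18, -2.29), pachytene (12 of 20, -1.51), early meiotic (7 of 21, -0.95) and cell cycle (14 of 20, -0.97) genes had more negative effects. Sertoli (16 of 25, 1.31), hedgehog (11 of 13, 1.51), retinoic acid (9 of 15, 0.93), p53 (11 of 15, 1.08), endothelial (5 of 10, 0.69) and immediate early genes (9 of 11, 2.84) had more positive ones, and Leydig cell genes (8 of 16, -0.89) more negative ones. On the genes that pass the filter at both ages 16 round spermatid members had a median of -2.32 and 13 elongating spermatid members -2.01. Of the 14 called lists only the endothelial one was not called there (camera adjusted p = 0.054). With an estimated correlation no list was called on these genes (lowest camera adjusted p = 0.307). Adjusted over the list alone the counts were the same, except 5 early meiotic, 13 pachytene and 18 elongating spermatid genes. The pan-germ-cell (camera adjusted p = 0.773), differentiating (0.358), peritubular (0.0756), immune (0.89), blood (0.168), epididymis (0.344), adipose (0.37), thyroid (0.344) and cholesterol (0.392) lists were not called. By fry the peritubular (adjusted p = 0.0099) and thyroid (adjusted p = 0.00066) lists had more positive effects, and the early meiotic call was lost (adjusted p = 0.0745). The largest positive differences were Ildr2 (6.91, SE 0.34), Atf3 (6.00, SE 0.33), Wfdc18 (5.75, SE 0.57) and Tnfrsf12a (5.65, SE 0.26). The largest negative ones were Dnajb8 (-6.94, SE 0.64), Prss55 (-6.21, SE 0.84), Eml6 (-5.08, SE 0.53) and Olfr127 (-4.49, SE 0.55), whose 4 probes match the telomeric repeat with scores of 8 to 10. Without a match, and chosen after seeing the data, they were Cyp11a1 (-4.13), Cst13 (-4.10), Cstdc6 (-3.98) and Plbd1 (-3.97). Over the called lists the camera adjusted p ranged from 3.5e-07 for round spermatids to 0.0403 for endothelial cells, and with an estimated correlation the adjusted p was 0.317 or higher for all 14 lists. The balance followed the scaling, with 4699 positive and 6478 negative differences under median scaling, which moved the median of all genes from 0.24 to -0.10. Slide as a block gave 6683 and 5098.

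The last comparison, 4 weeks against 1 week in WT, gives the developmental reference for the markers. Pachytene (20 of 20, median log2 6.26), round spermatid (20 of 20, 8.22), elongating spermatid (18 of 18, 9.504) and early meiotic genes (19 of 21, 2.66) rose with age. In 1-week WT 4 round and 5 elongating spermatid genes were well above background on fewer than 3 arrays. Their differences are fitted values against signals near background, so their size is uncertain. The other 16 and 13 had medians of 7.46 and 9.49, a choice made after seeing the data. At 4 weeks 5 undifferentiated and 3 GDNF genes were that dim, and the rest had medians of -1.68 and -1.90. Undifferentiated spermatogonial (19 of 25 lower, -1.90), GDNF (8 of 10, -1.62), Sertoli (21 of 25, -1.94), peritubular (10 of 10, -1.81), endothelial (9 of 10, -1.79), hedgehog (13 of 13, -3.33) and immediate early genes (9 of 11, -2.14) fell relative to the whole. The largest rises were the spermatid histones Hils1 (12.94) and H1f7 (12.14), Pbp2 (12.56) and Plaat5 (12.41, with a repeat score of 8), and the largest falls Bcan (-7.44), the fetal growth gene Dlk1 (-7.43), Sel1l3 (-7.26) and the steroid enzyme Hsd17b1 (-7.11). Of 23451 genes 7326 were higher and 11649 lower at 4 weeks. The camera adjusted p of these 11 lists ranged from 7.2e-11 for round spermatids to 0.0349 for endothelial cells, and with an estimated correlation the adjusted p was 0.251 or higher. The other lists were not called (camera adjusted p 0.0802 or higher), although fry called 21 lists in all. The list counts adjusted over the list alone were the same, apart from the Sertoli list, where 3 in place of 2 were higher. The ages lie on different slides and scan days, so age and slide cannot be told apart; with slide as a random block 7284 genes were higher and 11585 lower. Median scaling moved the median of all genes from -0.50 to -0.37.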

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

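Chosen only after the results were seen were the tests of the opposite strand, of slide and scan day, of the brighter genes and of an equal loss of germ cells, and the count of repeat matches; the other tests here were set before their values were known.

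The effect of Glis3KO2 differed between the ages for 12007 genes in the test of the difference itself, and for 145 of 190 genes named at either age. The lists that differed, as the median of the 4-week effect minus the 1-week effect, were undifferentiated spermatogonia (2.19), GDNF-responsive genes (1.998), early meiotic prophase (-0.95), pachytene spermatocytes (-1.51), round spermatids (-2.32), elongating spermatids (-2.29), Sertoli cells (1.31), Leydig cells (-0.89), endothelial cells (0.69), hedgehog (1.51), retinoic acid (0.93), cell cycle (-0.97), p53 targets (1.08) and immediate early genes (2.84); none was called with an estimated correlation, where the lowest adjusted p was 0.317. The genes were Ildr2 (6.91), Atf3 (6.00), Wfdc18 (5.75), Tnfrsf12a (5.65), Dnajb8 (-6.94), Prss55 (-6.21), Eml6 (-5.08) and Olfr127 (-4.49). Of 100 drawn splits that exchange genotypes within ages, 4 gave as many genes, the real one included, and the highest other split gave 13121. Every split that kept the 4-week genotypes apart gave at least 10028 genes and every other split at most 51, so the count follows the 4-week difference and the splits do not show that a difference between the ages is beyond chance. As many lists were called in 8 of the 100 splits (real 14, highest other 15), so chance cannot be excluded for the number of lists.

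Dnajb8, Prss55, Eml6 and Olfr127 belong to a set of genes raised at 1 week whose probes match the telomeric repeat. For Dnajb8 the 1-week rise was 3.66 and the difference between the ages -6.94, so the rise is only part of that difference. Of the 70 matching genes that rose by a log2 of more than 1, 18 have another measured probe without a match. Those other probes had a median log2 difference of -0.28 against 2.45 for the matching probes, and 1 of 18, for Krt8, rose by more than 0.5 of the value of its partner. For these 18 genes this argues that the signal belongs to the matching probe and not to the named gene. The matching probes were chosen for their rise and the others were not, which widens the gap. Raised genes without a match were not compared in this way. Over all tested probes with a score of 9 or more the median was only 0.27. Equal labelling of both strands, as from genomic DNA, is argued against by probes with the opposite strand, whose median was -0.15, and the mean of matching minus opposite probes differed between genotypes by 0.78 with no overlap of arrays (exact permutation p = 0.0286, the smallest possible). Slide and scan day are argued against by the mean of the matching probes, higher in Glis3KO2 by 0.53 on slide 1 and by 0.56 on slide 2. Repeat-bearing RNA that differs with genotype may be the source and was not tested further; the rise grew with the score, with a median of -0.14 for 616 genes at a score of 7, 0.27 for 87 genes at 9 and 1.54 for 8 genes at 11, and at 4 weeks the mean difference of the matching probes was -0.06 (exact permutation p = 0.3, smallest possible 0.1), while that of the opposite strand was 0.44 (exact permutation p = 0.1, the smallest possible).

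Undifferentiated spermatogonial genes were lower at 1 week and not at 4 weeks, relative to the whole of each array. Their median was -1.76 against 0.33 for Sertoli genes at 1 week, and 0.28 against 1.93 at 4 weeks. A recovery relative to Sertoli genes is therefore not shown. Dim probes as a whole were lower on the 1-week Glis3KO2 arrays. A difference in dim signal is argued against by the 6 members among the brighter genes, with a median of -0.93 and 5 of them called lower. It is also argued against by the 19 dimmer members, which differed between genotypes by -1.43 relative to genes of like brightness, with no overlap of arrays (exact permutation p = 0.0286, the smallest possible). An equal loss of all germ cells cannot be told apart: the spermatogonial mean minus the pan-germ-cell mean differed by -0.32 with overlapping arrays (exact permutation p = 0.429). Relative to differentiating spermatogonia, a comparison not set beforehand, the spermatogonial mean differed by -1.18 (exact permutation p = 0.0286, the smallest possible). Fewer undifferentiated spermatogonia, or less of their transcripts per cell, may each underlie the fall, and whole-testis RNA does not separate them.

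Of 112 groups of 4 arrays compared for a single far array, 4 had one, and chance gives about 1 in 20. They were Cpb2 in 1-week WT (gap over range 0.959, replicate 1), the number of saturated spots in 1-week WT (1, with 4 on replicate 4 and 3 on the rest), the elongating spermatid list in 1-week Glis3KO2 (0.891, replicate 3) and the hedgehog list in 1-week Glis3KO2 (0.843, replicate 3).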

How the results depend on the processing

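Alternatives chosen after seeing the data leave out repeat-matching probes, keep the brighter genes, use single slides, compare list members with genes of like brightness or keep genes measured at both ages; all others were planned, and the counts without 4-week Glis3KO2 replicate 3 belong to the planned set that leaves out each array. Over 256 results and 4758 alternative values, the gene counts at 4 weeks, between ages and in WT stayed within 1.5 times in every alternative run. The 1-week counts did not. Genes higher and lower at 1 week were 896 and 1372; they were 2926 higher with median scaling, 1446 higher with quantile normalization, 207 and 730 without a filter, 1655 higher with the stricter filter, 1564 and 2267 with all 14 arrays in 1 fit, 66 and 429 with slide as a block, 62 and 318 with a replicate block, 1999 higher with an intensity trend, and 2204 and 905 among the brighter genes. Leaving out 1 array gave 79 to 1199 higher and 279 to 2565 lower: 79 and 279 without WT replicate 1, 100 and 463 without WT 2, 83 and 337 without WT 3, 105 and 426 without Glis3KO2 1, 153 and 679 without Glis3KO2 4, and 2565 lower without WT 4. The cause was not tested, and the setting of brighter genes covers 11234 genes in place of 22468. Equal replicate numbers gave no clear sign of pairing: at 1 week deviations of equal-numbered arrays correlated at -0.17, -0.13, 0.02 and 0.16 across genes. At 4 weeks these correlations were 0.14, -0.31 and 0.07. Arrays with unequal numbers spread more widely at 1 week, from -0.36 to 0.45, so the check cannot settle whether the samples are paired.

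Glis3 at 1 week was -0.46 with normexp (adjusted p 0.205, range 0.00067 to 0.205) and -3.42 to -2.77 when 1 array was left out. The number of lists called at 1 week went from 8 to 0 with an estimated correlation and 5 with fry, at 4 weeks from 14 to 0, for the difference from 14 to 0, and in WT from 11 to 0 and to 21 with fry; leaving out 1 array gave 7 to 9, 12 to 14, 13 to 14 and 11 to 12.

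Some values changed sign. At 1 week median scaling gave 0.038 for round spermatids, 0.15 for adipose, 0.0153 for cholesterol and 0.21 for immediate early genes. Quantile normalization gave 0.18 for round spermatids, -0.0232 for peritubular cells, 0.24 for adipose, -0.0226 for thyroid and -0.19 for cell cycle genes (adjusted p 0.0154, range 0.0154 to 0.985). Normexp gave 0.0858 for round spermatids, 0.17 for adipose, 0.0299 for Papolb and 0.0359 for Hils1. The stricter filter gave 0.14 for round spermatids, the mean of probes -0.0880 for thyroid, slide as a block 0.0465 for adipose, -0.0217 for hedgehog and -0.00859 for cell cycle genes, and the brighter genes 0.23 for immediate early genes. At 4 weeks normexp gave 0.13 for epididymis. The cause was not tested. Leaving out 1 array gave -0.0409 to 0.17 for hedgehog, -0.16 to 0.11 for adipose, -0.0170 to 0.0654 for cell cycle, -0.0774 to 0.0205 for immediate early and -0.00722 to 0.25 for thyroid genes at 1 week, and -0.68 to 0.32 for adipose and -0.36 to 0.34 for blood genes at 4 weeks. Genes named at 1 week were no longer called in 168 values of the other alternatives and 217 leave-one-out values, and at 4 weeks in 7 and 8.

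The authors' series values equal the scanner values, so that alternative gave no separate value, and slide as a fixed block could not be fitted for age in WT. Leaving out an array of 3 leaves 2, and signal over background limits genes such as Glis3 that lie near it.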

Other observations

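Chosen only after the result was seen was the test of the slide shared with 4-week WT replicate 2; the other tests here were set before their values were known.

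X-linked genes were higher than autosomal genes in 4-week Glis3KO2. Of 785 X-linked genes 436 rose and 170 fell, with a median log2 difference of 0.82, while of 19971 autosomal genes 6914 rose and 6896 fell, with a median of 0.01. The hypothesis, set before this was computed, was that fewer meiotic and later germ cells, in which most of the X chromosome is silent, may raise X-linked genes as a class. It required the X median to be above the autosomal median in each of the 9 pairs of a Glis3KO2 and a WT array, and it was in 9 of 9; somatic or spermatogonial genes being more common on the X could give the same, and this was not tested. At 1 week the medians were 0.02 for 824 X-linked genes and -0.06 for 21223 autosomal genes. Over the pairs, which share arrays, the X median minus the autosomal median was 0.59 to 1.00 at 4 weeks. It was -0.0024 to 0.13 at 1 week and positive in most pairs, so the sign alone says little and the size sets the ages apart.

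4-week Glis3KO2 replicate 3 lay between WT and the other Glis3KO2 arrays, with a mean of the pachytene, round spermatid and elongating spermatid lists 1.21 above theirs. An effect of the slide it shares with WT replicate 2 is argued against, since that WT array lay only 0.18 above the other WT arrays in the same 58 genes. Mixing with WT RNA would need a WT fraction of 0.310 for the pachytene list (bootstrap interval 0.290 to 0.345). For the elongating spermatid list it would need 0.135 (0.042 to 0.172), a difference of 0.175. The prediction of equal fractions was not met. The intervals are over the genes of a list on this 1 array and hold no spread between samples. Glis3KO2 replicates 1 and 2 themselves lay at -2.84 and -3.69 in the elongating spermatid list, so mixing is not excluded. A milder effect in this sample may remain, and no biological explanation was tested. Without this array 8547 genes were higher and 7505 lower.

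Other splits of the arrays into groups of the same sizes show how far chance can be excluded. At 1 week 1 of 35 splits, the real one, gave as many genes as the 2268 called, the smallest share that 35 splits can give. This share under 5% argues against chance only if arrays can be exchanged freely over slides. The genotypes are not spread evenly over the slides, and the genes tested were those that passed the filter under the real labels, which can favour the real split. Exchanges within slides are too few for a share under 5%, and slide as a block gave 66 higher and 429 lower. Chance is therefore not excluded. The highest other split gave 1924 and exchanged WT replicate 4 with Glis3KO2 replicate 3; on WT replicate 4 the share of spots well above background was 76.7%, within the range of the Glis3KO2 arrays. In WT between ages 1 of 35 splits gave as many as 18975 genes, and the highest other gave 481; age and slide lie together there, so the splits do not separate them. At 4 weeks 10 splits are too few for a share under 5%; the real split gave 14645 genes, 1 of 10 as many, and the highest other 0. For the number of lists called by camera with the preset correlation, chance cannot be excluded at 1 week (14 of 35 splits gave as many as the real 8, highest other 14) or between ages in WT (17 of 35, real 11, highest other 15). At 4 weeks the splits are too few (2 of 10, real 14, highest other 14).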
